A study of Mus musculus with 2 samples.

How the data were processed

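Single-cell RNA sequencing was made from stroma of mouse salivary gland organoids. Organoids are small tissue-like aggregates grown in culture. The cells came from CD-1 mice, an outbred stock, at embryonic day 16, with an age label that adds 7 to that day. The meaning and unit of the added 7 are not given in the sources used here. There was 1 control library and 1 library of organoids with FGF2, a fibroblast growth factor that acts on fibroblasts and other mesenchymal cells. The dose and timing of FGF2 are not given in the sources used here. Per the labels' protocols, 5023 control cells and 10107 FGF2 cells were captured on the 10x Chromium system, a droplet method that tags the 3' end of each transcript with a cell barcode, and the libraries were sequenced on an Illumina instrument. Per the submitters' processing notes, Cell Ranger 4.0 and the mouse build mm10 were used. The filters on cells, the treatment of doublets, the normalization, the clustering and the tool and test behind the tables are not given in the sources used here.

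The values came from 3 tables deposited for the whole series, 1 for the clusters of the control library, 1 for the clusters of the FGF2 library and 1 for clusters of both libraries after integration. Which table belongs to which library was read from a word in each table's name that matches the description of 1 sample. The names of the tables speak of averages, but per the file headers each holds a comparison of each cluster with all other cells of the same table. The column of log ratios holds, per the file headers, the log of the average of the cluster over that of the other cells, and it was read as the natural log. This base was checked on genes listed with no positive cell in several clusters, for which the average in the other cells must come out alike. The median coefficient of variation of that average was 0.00169% over 8 control genes with the natural log against 0.0488% with base 2, and 0.0030% over 5 FGF2 genes against 0.0334%. The averages carry an offset of 1, so a ratio understates the difference of a low gene. The 2 columns of shares are fractions deposited by the authors and give the part of cells with a value above 0 in the cluster and in the other cells. They are printed as percentages. The authors' p-values and adjusted p-values come from single cells of 1 library. They are not printed, because cells are not replicates. No average per cluster, count per cell or number of cells per cluster was used here.

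The tables list only genes that differ between clusters. All listed entries had a p-value of the authors under 0.01, a natural log ratio of at least 0.25 in size, and a larger share of at least 25.1% (25.3% in the integrated table). The control table held 10368 entries for 4419 genes in 15 clusters, the FGF2 one 7725 entries for 3058 genes in 17 clusters, and the integrated one 3703 entries for 1208 genes in 14 clusters. The ratio of adjusted to raw p-values gave 19070, 20056 and 2802 genes tested. A gene that is not listed may still be expressed, evenly or at a low level. The integrated table rests on values made comparable between libraries, so its differences are differences of batch-integrated values and not of expression.

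The analysis had been laid out for averages per cluster before the data were examined, with a pseudocount of 0.1, a floor of 0.5 in 1 library, a size rule of 1.5-fold, 17 lists of cell type markers and 21 lists of gene functions. Because the tables hold log ratios and shares, the same numbers were applied to the percentage of cells with a count. For a gene listed in several clusters, the share over all cells equals the share in the other cells plus the cluster's part of all cells times the difference between the 2 listed shares. This sum is the same for every cluster of a gene. Least squares over the 2077 control genes and 1490 FGF2 genes listed in at least 2 clusters gave each cluster's part of all cells and, from it, each gene's share of cells with a count over the whole library. The cluster parts were not forced to add up and summed to 100.04%, 99.95% and 99.98% in the 3 tables. The residual root mean square was 0.0277 and 0.0279 percentage points in the library tables, close to the rounding of the listed shares. On simulated tables of the same shape, the largest error was 0.00888 (control, 4419 genes) and 0.0286 (FGF2, 3058 genes) points for a cluster's part and 0.053 and 0.0522 points for a gene's share. Of 60 genes simulated at least 1.5-fold higher 59 were called, and of 129 simulated lower 128 were called, with 0 and 1 wrong calls among 2317 genes. The changes were imposed at 2-fold or more, and the simulated shares obeyed the sum above, with rounding as their only error. They held no sampling of cells, depth difference or free RNA. The calls therefore check the arithmetic of the recovery and not the accuracy of calls in real cells.

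The 2 libraries were compared in genes listed in both library tables (2323 of the 5154 genes in either), after the floor. The size was the log2 ratio of the percentage of cells with a count plus 0.1. This measure saturates for genes found in nearly every cell and depends on depth. The depth per cell is unknown, so no thinning to a common depth could be had. The number of cells behind each table is not stated with it, and no interval was computed. With 1 library per group there was no test, no p-value and no replicate check. A gene counts as higher or lower where the ratio was at least 1.5-fold. For each list with at least 5 measured members, the median log2 ratio was set among 10000 random lists of the same size, matched on the mean share in 20 bins. The percentile describes these 2 libraries. It was noted where it lay below 2.5 or above 97.5. Named genes were the 12 with the largest ratio in each direction, list members given as examples, and Pdgfra, Fgfr1, Bmp2, Bmp4, Bmp7, Acta2, Col1a1 and Epcam. Some members of the lists are counted but not reported here by name.

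A cluster was called by a cell type only where at least 3 markers of 1 list were listed as higher and its 10 leading genes did not go against the name. Clusters were otherwise left with their number, as were those whose best list was fibroblast or smooth muscle, and integrated cluster 4 with 4 erythroid markers, even with at least 3 markers listed. The fibroblast-like naming foreseen for the stromal comparison was not usable, because most cells were stromal and a table of relative markers does not list what all clusters share. The stromal comparison therefore left out the clusters with an epithelial, glial, leukocyte or endothelial name. A share not listed for a left-out cluster was taken anywhere between 0 and 100%, and the ratio was taken at the bound nearest to no difference. Clusters of the libraries were matched by Spearman correlation of the listed log ratios over genes listed in both, with at least 20 genes. Of 5238 gene symbols, 5211 (99.48%) were in GENCODE M21, the annotation on GRCm38 (mm10), from which coordinates were taken. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used. The alternatives were other pseudocounts, floors, scalings and folds, other choices of clusters, each cluster left out in turn, and other correlations.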

Results

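The series asks how the stromal cells of salivary gland organoids fall into subpopulations, with and without FGF2. The data were 1 control library and 1 FGF2 library of single cells from CD-1 mouse glands taken at embryonic day 16, for which 5023 and 10107 cells were captured per the labels. The depth per cell was unknown. All values below are the percentage of cells of a library with a count of a gene, recovered from the authors' cluster comparisons, unless a sentence names the authors' deposited table. There was no replicate, so no difference between the libraries has a replicate check and none was tested.

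The cells of both libraries were largely stromal by the genes that lead the clusters. Non-stromal classes made up 5.85% of the control cells and 4.47% of the FGF2 cells. In the control library these were epithelial-like cells (2.83%, led by Wfdc18, Krt18 and Krt8), Schwann or glial-like cells (1.15%, Gap43 and Apod), macrophage-like cells (1.05%, Ccl6, Pf4 and Lyz2), basal epithelial-like cells (0.517%, Igfbp5, Krt14 and Itga6) and endothelial-like cells (0.298%, Fabp4, Ctla2a and Cd93). In the FGF2 library they were epithelial-like cells (2.88%, Chil1, Fxyd3 and Krt18), 2 leukocyte-like clusters and a small Schwann or glial-like cluster (0.307%). One leukocyte-like cluster (0.651%) was led by S100a9 and S100a8, calcium-binding proteins of neutrophils, and the other (0.640%) by Cma1, Mcpt4 and Mcpt2, proteases of mast cells. Proliferating-like clusters, led by mitotic and histone genes such as Top2a, Cenpf and Hist1h1b, held 10.2% of the control cells in 2 clusters and 4.42% of the FGF2 cells in 1 cluster. The remaining clusters kept their numbers.

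Pdgfra, the platelet-derived growth factor receptor of fibroblasts, was detected in 78.3% of the control cells and 84.2% of the FGF2 cells. In the authors' deposited table, control clusters 1 and 2 held Pdgfra in 96.8% and 93.3% of their cells, against 6.9% of the Schwann or glial-like cells and 17.0% of the macrophage-like cells. Control cluster 1 (14.5% of the cells) was led by Crabp1, Mmp3 and Cpxm1, with the matrix proteoglycan genes Lum and Dcn among its 10 leading genes. Control cluster 2 (13.9%) was led by Spp1, Cxcl13 and Saa3. Control clusters 3 (11.2%) and 5 (8.93%) carried contractile genes. Cluster 3 was led by Thbs1, Vegfd and Ptx3, and cluster 5 by Acta2, Actg2 and Tagln. Control clusters 0 (16.9%, Fbn2, Vegfd and Dlk1), 6 (7.16%, Mgp, Pmepa1 and Timp1) and 12 (0.828%, Ccl2, Mt1 and Hmox1) completed the stromal part. Control cluster 4 (10.6%) was led by AY036118, Gm42418 and Gm26917, and the genes listed for it had a median share of 10.9% in the cluster against 84.8% in the other cells. The epithelial-like control cluster had medians of 7.0% and 67.7%.

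In the FGF2 library, cluster 0 (16.4%) was led by Nptx1, Cdkn2a and Ctsl, and cluster 1 (14.1%) by Cck, Odc1 and Tac1, with the growth factor gene Hgf and the cytokine gene Il11 next. Cluster 2 (10.8%) was led by Igfbp3, Lpl and Clu. Cluster 3 (9.87%) was led by Ero1l, Il33 and Fam162a and also held the glucose transporter gene Slc2a1 among its leading genes. Cluster 4 (7.80%) carried contractile genes, led by Acta2, Tagln and Thbs1. Clusters 5 (7.33%, Igfbp5, Cd24a and Nr4a2), 6 (6.36%, Cavin2, Cemip and Ccl2), 7 (6.05%, Igfbp5, Il11 and Slpi), 8 (5.55%, Mgp, Pla1a and Ccl8) and 12 (1.96%, Ccl7, Ccl2 and Gm8797) were smaller. FGF2 cluster 10 (3.51%, Gm42418, Xist and Malat1) and cluster 13 (1.41%, Acta2, Tagln and Actb) had low median shares of their listed genes, 14.4% against 70.8% and 12% against 66.5%. The medians of the Schwann or glial-like FGF2 cluster 16 (16.1% against 62.7%) and of the mast cell-led cluster 15 (21.9% against 62.8%) were not far above these. Control clusters 4 and 9 and FGF2 clusters 10 and 13, picked after the data were seen with no set limit, together held 13.4% of the control cells and 4.92% of the FGF2 cells. With these 4 clusters left out and unlisted shares at the bound nearest to no difference, the counts of genes between the libraries given below were smaller.

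**Figure D1:**
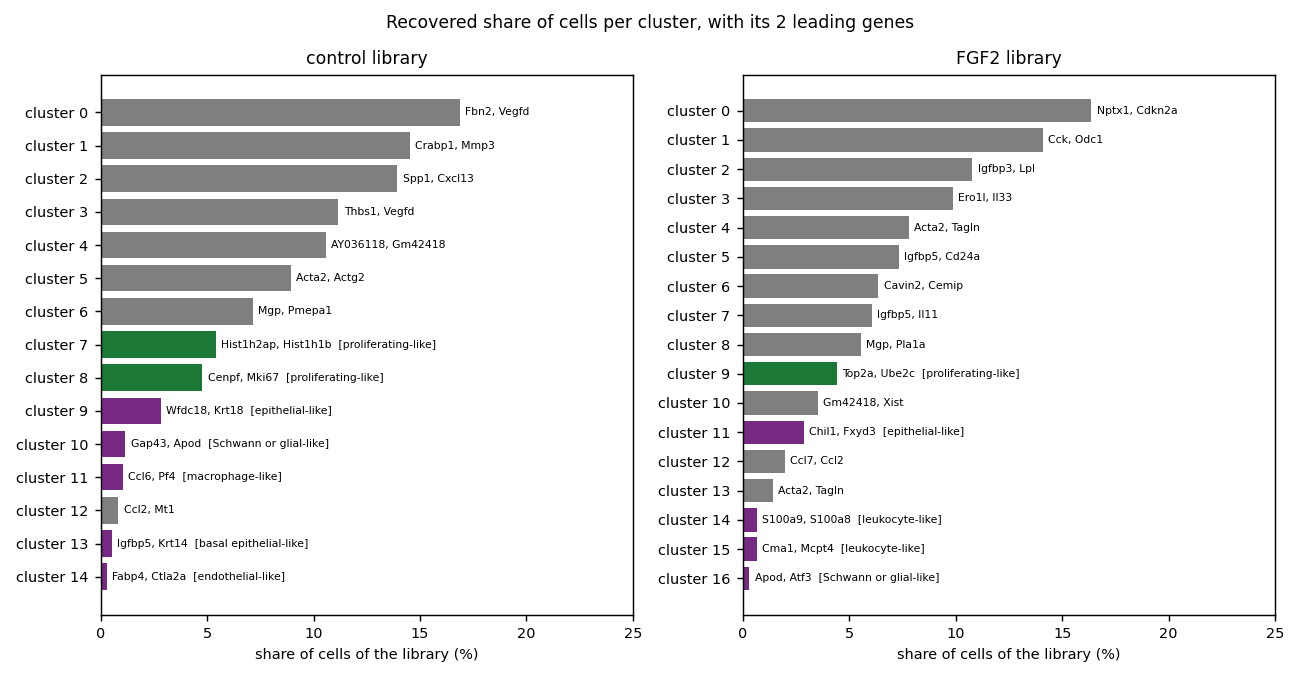
Share of the cells of each library (horizontal axis, %) held by each cluster, with its 2 leading genes, for the control library (left) and the FGF2 library (right). Green bars are proliferating-like and purple bars non-stromal classes, which sum to 5.85% and 4.47% of the cells.

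Clusters of the 2 libraries were matched to see which subpopulations had a counterpart. The contractile clusters (control 5 and FGF2 4) had the highest correlation of log ratios, a Spearman rho of 0.85 over 168 genes listed for both. The proliferating-like clusters control 8 and FGF2 9 followed with 0.83 over 190 genes, as did the control basal epithelial-like and FGF2 epithelial-like clusters with 0.83 over 414 genes. The Schwann or glial-like clusters matched at 0.75 over 518 genes, and the control macrophage-like cluster matched the FGF2 cluster led by S100a9 and S100a8 at 0.69 over 417 genes. Among stromal clusters, control 1 matched FGF2 2 at 0.68 over 105 genes, and control 12, led by Ccl2 and Mt1, matched FGF2 1 at 0.67 over 72 genes. These 7 pairs were each other's best match, but the last stromal matches were narrow. Control 1 also reached 0.66 with FGF2 5, 0.64 with FGF2 1 and 0.61 with FGF2 8, and FGF2 1 also reached 0.62 with control 2. Control clusters 0, 2, 3, 4, 6, 7, 9 and 14 had no partner by this rule, which does not mean that they had no counterpart. Control 3 reached 0.79 with FGF2 4 over 121 genes, but FGF2 4 matched control 5 better. Control 7 reached 0.76 with FGF2 4 over 25 genes, and 0.48 with FGF2 9 over 155 genes, 100% of them with the same sign. Control 4 reached 0.63 with FGF2 13 over 338 genes, 98.5% of them with the same sign. Genes are not independent replicates, and the correlations only match clusters.

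The comparison between the libraries asks which genes stromal organoid cells used with FGF2 and without it. By the size rule of 1.5-fold, 10 of 15 measured myofibroblast and TGF-beta response genes and 7 of 18 matrix genes were lower in the FGF2 library and none of either list was higher. A share cannot exceed all cells, so a gene found in most control cells could not be called higher. For such members of both lists, the lack of higher calls was fixed in advance. Acta2, the smooth muscle actin of myofibroblasts, was found in 89.9% of the control cells and 31.9% of the FGF2 cells, and Col3a1, a fibrillar collagen, in 92.4% and 32.0%. Of 8 chemokines and cytokines 6 were higher and 1 lower, and of 7 FGF and ERK feedback genes 2 were higher, 1 lower and 4 within the rule. Il11, a cytokine of activated fibroblasts, was found in 11.8% and 77.5% of the cells, Ereg, a ligand of the EGF receptor, in 13.1% and 67.4%, and Fosl1, a transcription factor induced by ERK signalling, in 16% and 64.0%. Of 2318 genes compared, 173 were higher and 351 lower in the FGF2 library, and 1794 lay within the rule. The median log2 ratio of all genes was -0.08, and -0.19 for the 1237 genes with a mean share of 25 to 75%. Of the 219 genes with a mean share under 10%, 112 were lower and 47 higher (median -0.62), so a lower rare gene was no exception.

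**Figure D2:**
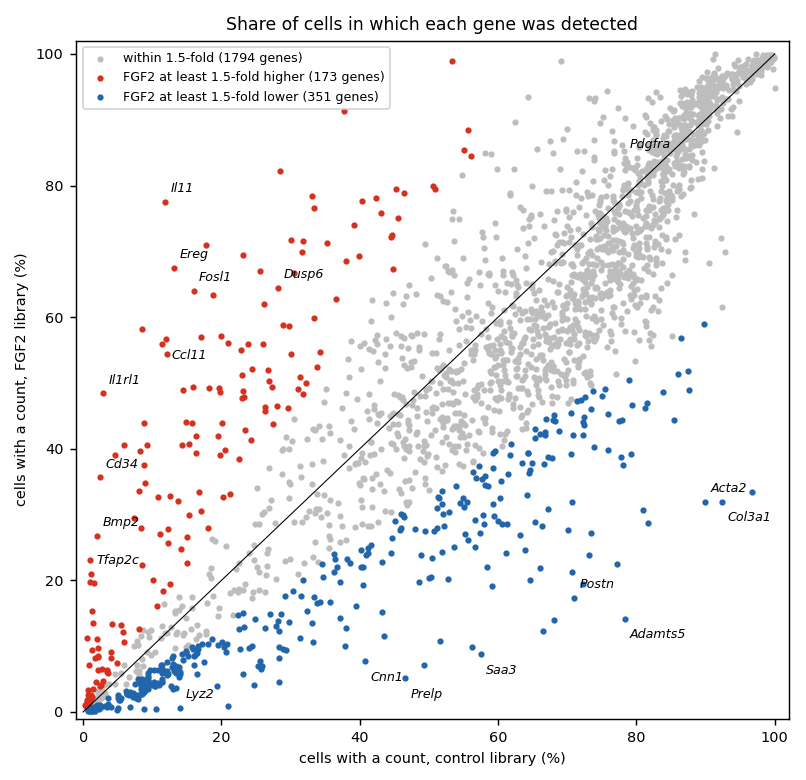
Percentage of cells with a count of each gene in the control library (horizontal) and the FGF2 library (vertical) for 2318 genes, with the line of equal shares. Red points are the 173 genes at least 1.5-fold higher and blue points the 351 at least 1.5-fold lower in the FGF2 library, and Acta2 lies at 89.9% and 31.9%.

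Of the 20 symbols listed for myofibroblasts and the response to TGF-beta, which include Cyr61 and Ctgf, older symbols of Ccn1 and Ccn2, 15 were measured, and 10 of them were lower, 0 higher. Tgfb1 (36.9%), Tgfb3 (33.9%) and Actg2 (25.2%) were listed in the control table alone. Postn, a matrix protein of TGF-beta-treated fibroblasts, was found in 71.0% of the control cells and 17.3% of the FGF2 cells, Cnn1, which binds actin in contractile cells, in 40.7% and 7.78%, and Tgfb2, a TGF-beta ligand, in 28.3% and 4.50%. Tagln, Myl9, Ccn2, Tgfbi and Lox were also lower. Tpm1 (93.6% and 91.6%), Tpm2, Ccn1, Fn1 and Ltbp2 lay within 1.5-fold. From a control share as high as that of Tpm1 or Acta2, no higher call was possible. The median log2 ratio was -1.01, below all random lists (percentile 0). The smooth muscle markers, whose 5 measured members all belong to this list too, had 4 of them lower (median -1.49, percentile 0). In the authors' deposited table, Acta2 was found in 66.0% of the macrophage-like and 62.1% of the Schwann or glial-like control cells, cell types that should lack it, and in 12.5% of the mast cell-led FGF2 cluster 15, at unknown depth. The control share of Acta2 stands against that background. Acta2 was also at 81.9% and 79.6% in control clusters 1 and 2, where the authors' deposited table lists it as lower than in the other cells.

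Of the fibrillar collagens and associated matrix genes, 18 were measured, 7 of them lower and 0 higher (median -0.30, percentile 0). Members with a high control share, such as Col1a1 and Dcn, could not be called higher. Col12a1 was found in 81.0% of the control cells and 30.6% of the FGF2 cells, Eln, the gene of elastin, in 43.2% and 15.2%, and Col6a2 in 78.0% and 37.5%. Col3a1, Col5a1, Col5a2 and Col5a3 were lower too. Col1a1, the main fibrillar collagen, was at 92.3% and 72.1%, within 1.5-fold, and the proteoglycan genes Dcn (84.8% and 91.7%) and Lum (51.2% and 69.0%) had the larger share in the FGF2 library. In the authors' deposited table, Col1a1 was found in 66.0% of the macrophage-like control cells and 21.9% of FGF2 cluster 15. Basement membrane genes were mostly within the rule, with Col4a5 (28.3% and 9.91%) the 1 lower member of 12 (median -0.22, percentile 20.7, and -0.33 at percentile 0.05 without the 4 clusters of low listed shares). Among 11 matrix proteases and inhibitors, Adamts1, Adamts5 and Mmp11 were lower and Mmp3 and Mmp13 higher (median 0.04, percentile 92.2). Adamts5, an aggrecanase, was found in 78.3% and 14.2% of the cells, Mmp3, the protease stromelysin 1, in 53.3% and 98.9%, and Mmp13, a collagenase, in 14.3% and 40.6%.

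**Figure D3:**
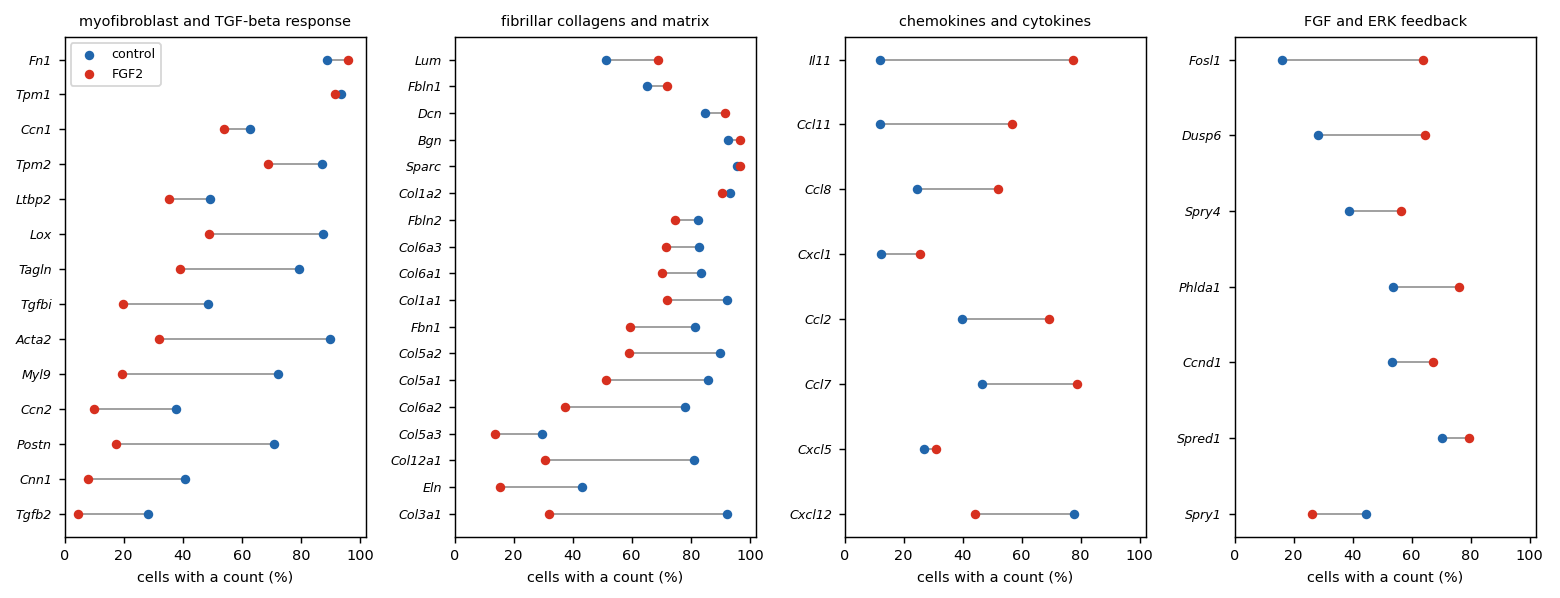
Percentage of cells with a count (horizontal axis) in the control (blue) and FGF2 (red) libraries for the measured genes of 4 lists (1 of the 15 myofibroblast genes is not drawn), with a line joining the 2 libraries. In the myofibroblast list 10 of 15 genes and in the matrix list 7 of 18 were at least 1.5-fold lower with FGF2, while 6 of 8 chemokines and cytokines were at least 1.5-fold higher.

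Chemokines and cytokines were higher in 6 of 8 measured members, with 1 lower (median 0.93, percentile 99.98). Besides Il11, Ccl11, which attracts eosinophils, was found in 12% of the control cells and 56.7% of the FGF2 cells, and Ccl2, which attracts monocytes, in 39.9% and 69.2%. Ccl7, Ccl8 and Cxcl1 were higher too, Cxcl5 lay within the rule, and Cxcl12, a stromal chemokine, was at 77.9% and 44.3%. In the authors' deposited table, Il11 was found in 99.3% of FGF2 cluster 7 and 96.4% of cluster 1, and in 21.9% of the mast cell-led cluster 15. FGF and ERK feedback genes had 7 measured members, 2 of them higher and 1 lower (median 0.51, percentile 99.82). Dusp6, a phosphatase that acts on ERK, was found in 28.2% and 64.4% of the cells, while Spry1, an inhibitor of receptor tyrosine kinase signalling, was at 44.6% and 26.4%, and Spry4, Spred1, Phlda1 and Ccnd1 lay within 1.5-fold, each with the larger share in the FGF2 library. The ETS factor genes Etv1 and Etv4, targets of FGF signalling, were listed in the FGF2 table alone, where they were found in 73.1% and 52.0% of the cells, as was Dusp5 at 32.4%. Of the same list, Spred2 (38.5%), Spry2 (35.2%) and Il17rd (12.1%) were listed in the control table alone. No value for these 6 genes in the other library was had, and an unlisted gene is not an absent one. Of 8 measured paracrine growth factors 2 were higher and 1 lower (median -0.09, percentile 62.0). The 2 were Ereg and Hbegf (16.3% and 39.4%), both ligands of the EGF receptor, and the lower one was Gdnf (2.45% and 1.12%). In the stromal comparison, with bounds, 2 of these 8 were higher and 0 lower.

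The BMP pathway had few measured members. Bmp2, a bone morphogenetic protein, was found in 1.99% of the control cells and 26.8% of the FGF2 cells, and was the 1 higher gene of 4 measured BMP ligands. Bmp4 was at 37.5% and 28.3%, and Bmp1 and Gdf10 also lay within the rule. Bmp7 was listed in the control table alone, at 0.935% of the cells. In the authors' deposited table, Bmp2 was found in 48.4% and 43.1% of FGF2 clusters 0 and 1 and in 4.7% of cluster 15. It was also found in 33.3% of the control endothelial-like cells, a cluster of only 0.298% of the control cells. Of 4 measured BMP antagonists 1 was higher, Grem1 (35.2% and 71.2%). Of 5 BMP target genes Id1 was higher (39.1% and 74.0%) and Id4 lower (33.2% and 10.6%), with a median of -0.01 at percentile 73.9. Fgfr1, the FGF receptor measured in both tables, was at 75.8% and 71.2%. Of 3 measured FGF ligands, Fgf7 (61.8% and 78.6%) and Fgf10 (40.2% and 32.2%) lay within the rule and Fgf5 (1.23% and 0.209%) was lower. In the stromal comparison, with bounds, 0 of these 3 were lower.

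Genes of stromal identity went both ways. Of 12 measured, 3 were higher and 2 lower (median 0.09, percentile 99.56). Cd34, a surface marker of fibroblast progenitors and endothelium, was found in 2.37% of the control cells and 35.6% of the FGF2 cells, Twist2, a mesenchymal transcription factor, in 31.6% and 69.8%, and Ly6a, which encodes Sca-1, in 55.6% and 88.4%. Vcam1 (72.2% and 42.1%) was among the lower ones, and Pdgfra, Thy1, Prrx1 and Twist1 lay within 1.5-fold. Cell cycle genes were lower in 15 of 20 measured members, such as Mki67 (12.2% and 5.77%) and Ccnb1 (10.8% and 4.46%). Their median of -0.82 lay at percentile 6.61 among lists matched on share, and the proliferating markers, 7 of 10 lower, at 22.4. The random lists were drawn from all compared genes, cell cycle genes among them, and had medians of -0.47 and -0.61. These percentiles therefore do not weigh against a drop shared by cell cycle genes. Without the 4 clusters of low listed shares, with bounds, 1 of the 20 cell cycle genes and 0 of the 10 proliferating markers were lower. The medians of both lists were then 0.00, a value that the bounds alone can give for rare genes. Mitochondrially encoded genes (11 measured, percentile 99.73) and ribosomal protein genes (20 measured, percentile 2.09) had no member outside the rule, with medians of 0.07 and 0.00. The measure saturates for genes found in nearly every cell, so this does not show unchanged expression.

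The 12 genes with the largest ratio upward were Upp1, Acpp, Ccr1, Tfap2c, Il1rl1, Cd34, Bmp2, Gldn, Dusp2, Clec4d, Trf and Csf2rb. Il1rl1, the receptor of interleukin 33, was found in 2.90% of the control cells and 48.4% of the FGF2 cells, Upp1, which cleaves uridine, in 0.917% and 23.1%, Trf, the gene of transferrin, in 4.64% and 39.0%, and Ccr1, a chemokine receptor, in 1.05% and 19.7%. The 12 with the largest ratio downward were Adamtsl1, Lyz2, Wfdc17, Ccl6, Insc, Prelp, Dock10, Foxd3, Chl1, Lurap1l, Saa3 and Tgfb2. Adamtsl1 was found in 20.9% and 0.856% of the cells, Prelp, a matrix proteoglycan, in 46.6% and 5.10%, Lurap1l in 49.3% and 7.14%, and Saa3, an acute phase protein, in 57.5% and 8.81%. Lyz2, the lysozyme of macrophages, was at 14% and 0.588%, and the Schwann lineage factor gene Foxd3 at 1.47% and 0.0993%. A gene had to be listed in both tables to be compared, so rare genes entered through rare cell types. In the library where they were lower, 11 of the 12 upward genes (all but Il1rl1) and 11 of the 12 downward genes (all but Lurap1l) were listed for non-stromal clusters alone, as were 96 of the 173 higher and 153 of the 351 lower genes. Without the 4 clusters of low listed shares, with bounds, 96 genes were higher and 136 lower, and Lyz2, Wfdc17, Ccl6, Chl1, Dock10, Foxd3, Insc and Epcam had no ratio left of at least 1.5-fold. Of the 4 lists above the random lists, FGF and ERK feedback (percentile 99.7, 2 of 7 higher) and chemokines and cytokines (percentile 100, 4 of 8 higher) stayed there, stromal identity went to percentile 65.6 and the mitochondrially encoded genes to 0.05. Of the 5 lists below, the Schwann or glial and ribosomal protein lists went to percentile 50, and the basement membrane list came to lie below at 0.05. On the scale of -ln(1 - share), 552 genes were lower.

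The stromal comparison left out the non-stromal clusters to ask whether these differences lay in the stromal cells. Of 2299 genes, 123 were higher and 190 lower in the FGF2 library by the same size rule, each ratio taken at the bound nearest to no difference, and 1986 lay within it. The same 12 genes led upward. Bmp2 was found in at most 2.01% of the control stromal cells and in 24 to 28.0% of those with FGF2, and Ccr1 in at most 0.631% and in 16.3 to 20.3%. Free RNA was not examined as a source of the Ccr1 counts. Downward, Igfbp2, Mylk, Tenm3 and Adamts5 joined Adamtsl1, Lyz2, Wfdc17, Ccl6, Prelp, Lurap1l, Saa3 and Tgfb2. Mylk, the kinase of myosin light chain, was found in 69.7 to 70.0% of the control and 10.3 to 12% of the FGF2 stromal cells, Adamts5 in 81.2 to 82.5% and 10.3 to 14.7%, and Prelp in 48.4 to 49.2% and 2.70 to 4.37%. The myofibroblast list again had 10 of 15 members lower (median -1.07, percentile 0), the matrix list 7 of 18 lower (median -0.31, percentile 0), the chemokine list 6 of 8 higher and 1 lower (median 0.80, percentile 99.95) and the FGF and ERK feedback list 2 of 7 higher and 1 lower (median 0.45, percentile 99.93). Cell cycle genes had 1 lower member of 20 (median -0.17, percentile 3.14), but their bounds had a median width of 6.21 points in the control and 4.68 in the FGF2 cells, wide for shares of this size, and the proliferating-like clusters stayed in, so where their difference lay was not settled. With the clusters where the authors listed Pdgfra as lower left out as well, which removed control clusters 4, 5 and 6 and FGF2 cluster 13, 74 genes were higher and 94 lower. Adamtsl1, Igfbp2, Lyz2, Wfdc17, Ccl6 and Dock10 then had no ratio left of at least 1.5-fold. Smooth muscle genes were the best-matched list of control clusters 4 and 5 and FGF2 cluster 13, which this left out, and of control cluster 3 and FGF2 cluster 4, which it kept. Control cluster 5 was thus left out while its best match, FGF2 cluster 4, stayed in. The control clusters removed held 10.6%, 8.93% and 7.16% of the cells and FGF2 cluster 13 held 1.41%, so these counts compare unlike sets of clusters. The lower genes numbered 114 without control cluster 4 and FGF2 clusters 10 and 13, and 357 with unlisted shares at the library value. In the first of these, Csf2rb, Lyz2, Wfdc17, Ccl6 and Dock10 had no ratio left of at least 1.5-fold. Dock10 also had none without control cluster 0, 1 or 2.

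Markers of other cell types went both ways. Of 6 measured Schwann or glial markers 5 were lower in the FGF2 library, such as Cdh19 (1.67% and 0.188%), and S100b was higher (19.8% and 39.1%), with a median of -1.59 at percentile 0.8. In the stromal comparison S100b was at 15.1 to 20.1% and 39.5 to 40.5%, and the bounds of the other 4 members measured there overlapped, which leaves open where their difference lay. Of 6 epithelial markers 3 were higher and 1 lower (median 0.56, percentile 94.5), with Epcam, an epithelial adhesion protein, at 1.85% and 4.54% and Krt18 at 4.22% and 13.3%. With the non-stromal clusters left out of both libraries, Krt18 was at most at 2.43% in the control and at 10.02 to 11.7% in the FGF2 cells, and the bounds of Epcam, at most 1.48% and 0.869 to 2.54%, overlapped. Of 5 basal or myoepithelial markers 3 were higher (median 0.68, percentile 92.6). Of the 4 of them in the stromal comparison 0 were outside the rule, with overlapping bounds for 3. Without FGF2 cluster 11, left out of that library alone, the median of this list was -0.99, and without control cluster 10, left out in the same way, that of the Schwann or glial list was 0.13. Without the 4 clusters of low listed shares, with bounds, 0 Schwann or glial markers were lower, 1 epithelial and 0 basal markers were higher, and the medians of these 3 lists were 0.00, a value that the bounds alone can give for rare genes.

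In mm10, Acta2 lies on chromosome 19 from 34241090 to 34255590 on the minus strand, Bmp2 on chromosome 2 from 133552159 to 133562885 on the plus strand, and Pdgfra on chromosome 5 from 75152292 to 75198215 on the plus strand. Cd34 lies on chromosome 1 from 194938819 to 194961279, Il1rl1 on chromosome 1 from 40429570 to 40465415, Col1a1 on chromosome 11 from 94936224 to 94953042, Fgfr1 on chromosome 8 from 25513654 to 25575718, Bmp4 on chromosome 14 from 46383520 to 46390669, Bmp7 on chromosome 2 from 172868012 to 172940321 and Epcam on chromosome 17 from 87635979 to 87651129. All 10 are protein-coding genes. The tables give values per gene and no position within it.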

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

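Of the alternatives below, the scale of -ln(1 - share), the clusters of low listed shares left out (control 4 and 9, FGF2 10 and 13), the unlisted shares at the library value and the limit on the authors' adjusted p were chosen only after the data were seen. Of the 56 named-gene ratios of at least 1.5-fold, 1978 alternative values were computed. Of these, 23 were under 1.5-fold and 0 had the other sign. Another pseudocount, floor, fold or scale cannot turn the sign of a ratio, and overlapping bounds give a ratio of 0. The lack of turned signs therefore says little about stability. The 1978 values include each cluster left out in turn, so the 23 are not a rate for any 1 setting. Most of the 23 came from leaving out the clusters of low listed shares or the stromal clusters with Pdgfra listed as lower. With 2-fold in place of 1.5-fold, 96 genes were higher and 174 lower (173 and 351 before), by construction. On the scale of -ln(1 - share), 552 genes were lower, a scale that widens differences between high shares. Without the clusters of low listed shares, 96 genes were higher, 136 lower and 2 lists lay above the random lists (4 before; stromal identity and mitochondrially encoded genes left), with bounds that pull ratios to 0. Below them lay 5 as before, but basement membrane and mitochondrially encoded genes had taken the place of the Schwann or glial and ribosomal protein lists. In the stromal comparison the lower genes then numbered 114 (190 before), and with unlisted shares at the library value 357. With the stromal clusters in which Pdgfra was listed as lower left out, 74 genes were higher and 94 lower (123 and 190 before). This removal was uneven. It dropped control clusters 4, 5 and 6 (10.6%, 8.93% and 7.16% of the cells) but of the FGF2 stromal clusters only 13 (1.41%). Contractile control cluster 5 was dropped while its best match, FGF2 cluster 4, was kept. The smaller counts thus follow in part from the way this alternative is built. With a floor of 2% in 1 library, 3 lists lay below the random lists (5 before), because the Schwann or glial list had too few members left and ribosomal proteins went to percentile 2.53. With each cluster left out in turn, the genes higher ranged from 164 to 180 and lower from 313 to 370, the lists above from 3 to 5 and below from 3 (without control cluster 10, the Schwann or glial-like one) to 5, and the stromal genes higher from 118 to 128 and lower from 177 to 247. The list medians that turned were those of Schwann or glial markers, from -2.06 to 0.13 (without control cluster 10), and of basal or myoepithelial markers, from -0.99 (without FGF2 cluster 11) to 0.89. In both, the cluster left out of 1 library carried these markers while its match in the other was kept, so the turn follows from the way the alternative is built. All other values of the main counts, 205 under settings fixed before the data were examined and 8 under added ones, lay within 1.5 times the main ones. Rescaling without the 50 highest genes, the median over clusters, and the pseudocount, floor and highest other cluster within a library were not run, because the tables hold no averages. No paired analysis was possible because there was 1 library per group. The unknown depth limits every share.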

Other observations

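The tests on depth, on free RNA over the myofibroblast list and for Acta2, on a difference other than FGF2 and on nuclear RNA, and the shuffle of cluster averages, were chosen only after the result was seen. The tests without the clusters of low listed shares and on the genes of macrophage-like cells were written before their results.

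Housekeeping and stress genes mostly lay within the size rule between the libraries. The measure saturates for genes found in nearly every cell, so a share within the rule does not show unchanged expression. Of 16 measured hypoxia and glycolysis genes 1 was lower by the size rule with FGF2, Ndrg1 (27.8% of control and 13.0% of FGF2 cells), and the median log2 ratio was 0.02 at percentile 43.5 among random lists. Of 12 immediate early and heat shock genes 1 was lower, the stress-induced factor Atf3 (7.57% and 2.09%), with Jun, Fos and Egr1 within 1.5-fold (median -0.01, percentile 76.1). The 5 measured cholesterol synthesis genes (median -0.11, percentile 72.9) and the 3 interferon response genes (median -0.02) were all within the rule. Of 4 Wnt pathway genes, the secreted inhibitor Sfrp2 (48.8% and 23.9%) and the receptor Fzd1 (66.3% and 28.2%) were lower, with a list median of -0.64. Fibroblast markers had 2 of 9 lower, Postn and Col3a1 (median -0.04, percentile 52.0). The other cell type lists had few measured members. Of 3 chondrogenic markers Col9a1 and Col9a3 were higher and Sox9 within the rule, of 3 osteogenic ones Col11a1 (77.2% and 22.5%) was lower with Runx2 and Spp1 within the rule, and the 1 adipocyte marker, Lpl (85.5% and 44.3%), was lower. The 4 pericyte and 2 other leukocyte markers were within the rule, Plvap was higher and Flt1 within the rule among endothelial markers, the 1 neuron marker Stmn2 was higher, and of 2 macrophage markers Lyz2 was lower. In the stromal comparison, with bounds, 0 of 2 measured chondrogenic markers were higher and Stmn2 lay within the rule. There, 0 of 12 immediate early and heat shock genes were lower and 1 of 4 pericyte markers was lower. No proacinar, erythroid or skeletal muscle marker was listed in both tables.

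Several growth factor and differentiation genes were listed in 1 library table, so no ratio was had. In the FGF2 library, Cck, a peptide hormone, was found in 84.7% of the cells, Hgf, the ligand of the receptor Met, in 50.6%, Il33, the ligand of Il1rl1, in 41.7%, Areg, a ligand of the EGF receptor, in 34.5%, and the cell cycle inhibitor gene Cdkn2a in 61.5%. Aqp5, a water channel of proacinar cells, was found in 9.72%. In the control library, Vegfd was found in 53.5%, Igf1 in 41.3%, Actg2 in 25.2% and Myh11, a smooth muscle myosin, in 15.6%. These genes were chosen after their values were seen. In the integrated table, cluster 4 (6.71% of the cells) was led by the haemoglobin genes Hba-a1, Hbb-bs and Hba-a2, and in the authors' deposited table Hba-a1 had a natural log ratio of 3.94 there, with a value above 0 in 38.6% of its cells against 30.2% of the others. No haemoglobin gene was listed in either library table, and integrated values above 0 are not counts.

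Myofibroblast and TGF-beta response genes had lower shares with FGF2. A difference in depth was expected to move lists of the same mean share alike, and the list median lay below all of those random lists, at percentile 0. That percentile is the one that described the pattern, and genes of the same mean share need not respond to depth alike. With the depth per cell unknown, this cannot decide on a difference in depth, which stays open. Large drops were not limited to this list. In the authors' deposited table, AY036118 was found in 98.9% of control cluster 4 and 96.4% of the other control cells. In the FGF2 library it was found in 39.2% of cluster 11 and 33.2% of the other cells, and the cause was not tested. Clusters of low RNA content are argued against as the whole cause of the lower myofibroblast shares by the median of -1.04 without them. Free RNA in the control library is argued against as the whole of the control share for 7 of the 8 lower members with a listed share in macrophage-like cells. For these 7, the share over all control cells was at least 1.5-fold that in macrophage-like cells (Ccn2 and Tgfb2 had no such share). In Schwann or glial-like control cells the same held for 5 of 10 members, with Acta2, Tagln, Postn, Tgfbi and Tgfb2 the exceptions, of which Postn (100% of those cells), Tgfbi (62.1%) and Tgfb2 (44.8%) were listed as higher there in the authors' deposited table. For Acta2, the exception in both, 66% of macrophage-like cells had a count against 89.9% of all control cells, so how much of its share, or of that of Tagln (79.2% against 53.4% of Schwann or glial-like cells), is free RNA stays open. These comparisons do not test whether free RNA adds to the gap between the libraries. In FGF2 leukocyte-like clusters the listed shares were 21.5% for Tagln and 32.3% for Lox in cluster 14, and 12.5% for Acta2 and 18.8% for Lox in cluster 15. An effect of FGF2 on the myofibroblast state is a hypothesis that cannot be told apart from any other difference between these libraries, because there was 1 library per group.

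Lyz2, Wfdc17 and Ccl6 lead the control macrophage-like cluster, and in the authors' deposited table they were also found in 13.3%, 9.8% and 8.0% of the other control cells. Free RNA from macrophage-like cells may be the source. The test written beforehand expected a positive correlation, across 211 genes listed as higher in that cluster alone, between the log ratio and the share of the other cells with a count, and took a value under 0 as evidence against it. The rho was -0.142, but that reading was wrong, because the other cells' average is the denominator of the log ratio. With the cluster averages shuffled among genes, rho ranged over the central 95% from -0.349 to -0.0834, from -0.492 to -0.266 or from -0.595 to -0.401 at 3 assumed scales of the averages, so -0.142 lay inside at 1 scale and above, on the side of free RNA, at 2, and since the scale is unknown this stays open, with no biological explanation tested.

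FGF2 clusters 10 and 13 were examined for RNA known to stay in the nucleus, which nuclei or leaky cells in cluster 10 would raise and cell parts without a nucleus in cluster 13 would lower. Of 8 such genes, 5 of the 5 listed for cluster 10 were higher and 6 of the 6 listed for cluster 13 lower, but 42.3% of all genes listed for cluster 10 were higher and 76% of those listed for cluster 13 were lower, so 1.3% and 19.2% of random draws of as many listed genes would do the same. Without Malat1, Xist and Meg3, which had been seen among leading genes, 2 and 3 genes were left and these chances were 17.8% and 43.9%. In the authors' deposited table, the average of Malat1 plus 1 was 20.01-fold lower in cluster 13 than in the other cells and that of Neat1 15.9-fold, while Kcnq1ot1 was higher in cluster 10 although it was found in 17.8% of its cells against 66.7%. Whether such droplets are part of these clusters stays open, and no biological explanation was tested.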
